A study of Homo sapiens with 5 samples.

How the data were processed

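The series holds 5 arrays of the Affymetrix Human Genome U133A type, 1 each for U937 cells at 0, 1, 2, 3 and 6 h with anisomycin, at 1 µM at all times but 0 h, per the labels. Per the labels' protocols, 5 µg of total RNA was converted to cDNA, biotin-labelled cRNA was made by in vitro transcription, and each RNA was hybridised to 1 array. The deposited values are linear intensity values, 1 signal per probe set and array, never negative and with 1 decimal. The summary algorithm, the software, any scaling and any background step are not given in the sources used here.

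Of 22283 probe sets, 68 are controls. Probe sets were named from the platform's annotation table as supplied, which can be old: 19071 had exactly 1 gene symbol, 1043 had several and 2169 were not listed and are unnamed here. Entrez identifiers of 19059 probe sets were matched to a RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. No coordinates are given, because the files name no genome build. Probe sets with several symbols or none stayed out of the gene counts. The remaining probe sets represent 11963 genes. Some items are not reported here.

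The design was set before the data were examined, and so were the gene lists, the thresholds, the rule for named genes and all alternatives except those named below as added. The rule was to use signals as deposited only if the trimmed means of the arrays, with 2% left out at each end, lay within 5% of each other. They did not, so each array was multiplied by a factor (0.814, 1.03, 1.24, 0.913 and 1.12 at 0, 1, 2, 3 and 6 h) that brought its trimmed mean to 190 units. This fixes the bulk of the probe sets and hides any change of total messenger RNA per cell. A floor was then set at the mean over arrays of the 40th percentile of the probe sets, 23.8 units, and log2 was taken. A gene was represented by its probe set with the highest mean signal over the 5 arrays and was measured at a time if it lay above the floor on that array or on the 0 h array. Where it lay at the floor on 1 of these, the ratio is a lower bound and is written as at least N-fold. Folds of weak genes depend on the floor and on the unknown background step.

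With 1 array per time there is no SD between replicates and no p-value. Genes were counted past a fixed 2-fold mark. As the only available error, the log2 ratios of the 2 brightest probe sets of a gene were compared over 2365 to 2434 genes, and the SD of a single probe set's ratio was taken from their differences. It was 0.30, 0.33, 0.33 and 0.38 at 1, 2, 3 and 6 h, with 0.24 to 0.29 in the brighter genes and 0.36 to 0.44 in the dimmer ones. It leaves out differences between cultures, RNA preparations and labelling, so it is a lower bound on the error.

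The 28 gene lists cover immediate early genes, MAPK feedback, stress kinases, NF-κB targets, cytokines, pro-apoptotic BCL2 family, anti-apoptotic genes, the death receptor pathway, caspases and executioners, ATF4 and CHOP stress, heat shock proteins, NRF2 targets, interferon-stimulated genes, cytosolic ribosomal proteins, ribosome biogenesis, translation factors, mRNA decay factors, snoRNA host genes, histones, mitosis, DNA replication, cholesterol synthesis, mitochondrial respiration, the proteasome, monocytic markers, other cell types, reference genes and numbered zinc finger genes. Some genes are in more than 1 list. Each list's median log2 ratio was given its percentile among 10000 random lists of the same size matched on mean signal in 20 bins, with members at the floor kept at their bound. Such a percentile describes these arrays and is not a p-value. Percentiles below 2.5 or above 97.5 are spoken of as apart from random lists.

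Named genes are, at each time, the 10 largest increases and 10 largest decreases among genes past 2-fold, above the floor on both arrays, not represented by an _x_at probe set, and with all other measured probe sets going the same way. Added to these are the 5 largest bounds in each direction, up to 4 members of each list with the largest change at any time, and a fixed set of apoptosis, stress and reference genes. Genes without a proper symbol were left out. Genes outside this rule are named only where the text says that they were chosen after their values were seen.

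Overlaps between times share the 0 h array. Unchanged arrays were therefore simulated 100 times against the 0 h array with the SD above, and the overlap, correlation and covariance of these are given beside the measured ones. Ordered changes were counted under the 60 orders of the arrays, an order and its mirror counting as 1.

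The procedure was tested on simulated data built from the mean of the 5 arrays with that SD, with changes placed in genes whose 0 h signal was over 4 times the floor, so that weaker genes were not tested. Of 50 genes changed by 1.5 on the log2 scale, 47, 44, 47 and 40 were recovered at 1, 2, 3 and 6 h, and all 50 of those changed by 3. Among unchanged genes, 0, 3, 7 and 16 were falsely higher and 4, 13, 12 and 36 falsely lower. These counts are likely too low, because the SD is a lower bound on the error and was the same for dim and bright genes. The unchanged genes numbered 7882 at 1, 2 and 3 h and 7927 at 6 h. Of 40 unchanged lists, 3, 4, 1 and 1 lay outside the 2.5 and 97.5 percentiles, and a list shifted by 0.5 lay at percentile 100 at each time.

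Alternatives tried were floors at the 25th and 60th percentile, no floor with a pseudocount of 1, quantile normalization, median scaling, cyclic loess, scaling on ribosomal protein genes, thresholds of 1.5-fold and 3-fold, the median over probe sets, leaving out _s_at and _x_at probe sets, which can match several transcripts or genes, the 1 h array as reference, support from a neighbouring time, list members above the floor on both arrays only, and 10 bins for random lists. Scaling to the poly-A spikes, scaling to the hybridisation spikes and support from a second probe set were chosen after seeing the data. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess.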

Results

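RNA levels were measured in U937 cells, a human line from a histiocytic lymphoma that carries features of monocytes, during treatment with 1 µM anisomycin. Anisomycin is an antibiotic that blocks peptide bond formation on the ribosome and activates the stress kinases JNK and p38. RNA was taken at 0, 1, 2, 3 and 6 h and hybridised to oligonucleotide arrays with 22283 probe sets. There was 1 array per time, so the number of arrays limits the precision, no value has a replicate check, and no difference between times was tested. The labels name genes in anisomycin-induced apoptosis as the subject of the study, and each treated time was therefore compared with 0 h. There was no untreated array at 1, 2, 3 or 6 h. Effects of anisomycin therefore cannot be told apart from those of time in culture or handling. Deposited signals had trimmed means of 234, 185, 154, 209 and 170 units at 0, 1, 2, 3 and 6 h, and the arrays were brought to a common trimmed mean. After scaling, between 58.8% and 61.4% of the probe sets lay above the floor of 23.8 units on each array.

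Every ratio below is relative to the bulk of the probe sets on an array. The probe sets for the bacterial poly-A spikes, RNAs added before labelling, had scaled medians that were 0.36, 1.56, 1.64 and 1.57 higher on the log2 scale at 1, 2, 3 and 6 h than at 0 h. The hybridisation spikes, which are added after labelling, were 0.01, 0.36, 0.44 and 0.50 higher. Scaling to the poly-A spikes would place the median gene at -0.29, -1.49, -1.56 and -1.41, and scaling to the hybridisation spikes would place it at 0.02, -0.39, -0.45 and -0.48. With poly-A spike scaling, the medians of 2, 2 and 1 of the 28 gene lists were above 0 at 2, 3 and 6 h. Histones were above 0 at all 3 of these times, with 0.38, 0.26 and 0.22, and immediate early genes at 2 and 3 h, with 0.71 and 1.06. With hybridisation spike scaling 5, 4 and 6 list medians were above 0. Of the 33 list medians apart from random lists over the 4 times, poly-A spike scaling turned the sign of 21 and hybridisation spike scaling that of 9, so the directions of lists below are relative. The ratio of 3' to 5' signal lay between 0.957 and 1.04 for GAPDH and between 1.27 and 1.53 for ACTB, with the highest ACTB values at 3 and 6 h.

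**Figure D1:**
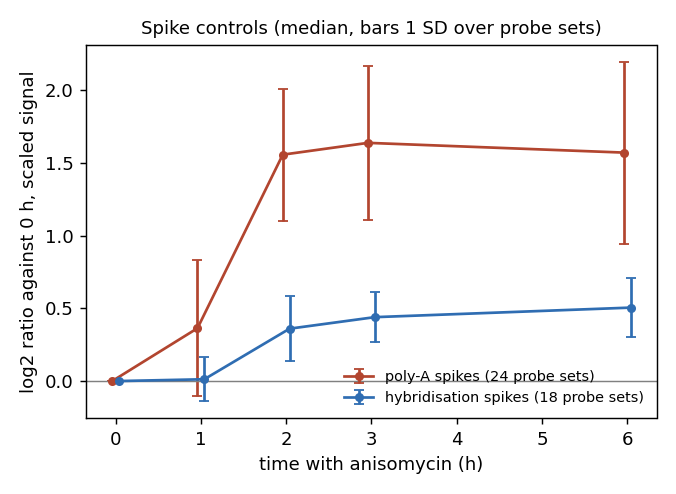
Spike controls against time with anisomycin in hours, as log2 ratios of scaled signal against 0 h. Points are medians over 24 poly-A or 18 hybridisation probe sets and bars are 1 SD over probe sets. The poly-A spikes stand at 1.56, 1.64 and 1.57 from 2 h on, and the hybridisation spikes at 0.36, 0.44 and 0.50.

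At 1 h the cells held more RNA of immediate early transcription factors. FOS, a subunit of the AP-1 transcription factor, was 21.1-fold higher than at 0 h, with a log2 ratio of 4.40. JUN, its partner, was 30.6-fold higher, a log2 ratio of 4.94 with 2.53 and 5.10 from its other probe sets. EGR1, a zinc finger transcription factor, was 11.4-fold higher by its brighter probe set, a log2 ratio of 3.52 against only 0.65 from the other. DUSP1, a phosphatase that inactivates MAP kinases, was 9.47-fold higher, and the histone gene H2AC6 was 7.88-fold higher. The interleukin-8 gene CXCL8 had a log2 ratio of 1.96 and TNF one of 1.14.

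In all, 116 of 8393 measured genes were at least 2-fold higher at 1 h and 40 were at least 2-fold lower. Of these, 12 were at least 4-fold higher and 0 were at least 4-fold lower. Single probe set ratios scattered around the others of the same gene with an SD of 0.30 on the log2 scale. Among called genes with a second measured probe set, the second went the same way for 16 of 20 higher genes but for only 2 of 9 lower genes. Among the lower genes were SFTPC at -1.31, TMEM184B at -1.23, HINFP at -1.19 and RETREG3 at -1.07.

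Immediate early genes had a median log2 ratio of 0.83 at 1 h, with 12 of 26 members higher, 0 lower and 14 between. FOSB, at 2.91, ATF3, at 2.69, EGR3, at 2.44, and KLF6, at 2.10, were among the largest changes. The median lay at percentile 100 of 10000 random lists matched on mean signal. MAPK feedback genes had a median of 0.31, with 3 of 16 higher, at percentile 99.98, and DUSP2 stood at 1.92. Histone genes had a median of 0.88, with 9 of 20 higher and 0 lower, at percentile 100. Among them, H2BC12L had a log2 ratio of 1.67, H1-2 one of 1.60 and H2BC12 one of 1.25. Of the stress response genes downstream of ATF4 and CHOP, 3 of 23 were higher, with PPP1R15A at 1.31 and DDIT3, which encodes CHOP, at 1.29, while the list median was -0.09. The mRNA decay list held 1 higher member, ZFP36, which encodes an AU-rich element binding protein, at 1.58. The heat shock list held 1 higher member of 18, DNAJB1, at 1.08. Small medians apart from random lists were those of numbered zinc finger genes, 0.15 at percentile 99.65, of cytosolic ribosomal proteins, 0.09 at percentile 99.8, and of the respiratory chain, -0.07 at percentile 1.64.

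Several genes had no signal above the floor at 0 h and are given as lower bounds. MINDY1 was at least 4.07-fold higher at 1 h, CCNO at least 3.36-fold and PTGS2, the inducible prostaglandin synthase, at least 3.28-fold. In the other direction FOXRED2 was at least 3.00-fold lower and HDAC7 at least 2.53-fold lower.

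**Figure D2:**
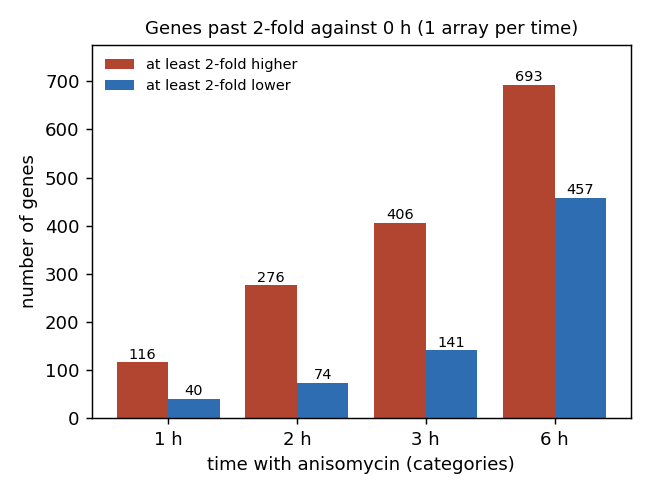
Number of genes at least 2-fold higher (red) or lower (blue) than at 0 h, by time with anisomycin as categories, 1 array per time. Higher genes number 116, 276, 406 and 693, and lower genes 40, 74, 141 and 457; all are relative to the bulk of the probe sets, and with poly-A spike scaling lower genes outnumber higher genes at each time.

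At 2 h the same early regulators were higher still. FOS was 44.9-fold, JUN 56.0-fold and DUSP1 29.4-fold higher than at 0 h. IER3, an early gene linked to cell survival, was 20.6-fold higher, against a log2 ratio of 1.31 at 1 h. CYP1A1, a cytochrome P450 that is a classic target of the aryl hydrocarbon receptor, was 17-fold higher. CDKN1A, which encodes the cell cycle inhibitor p21, was 12.4-fold higher.

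A total of 276 of 8451 genes were at least 2-fold higher at 2 h and 74 were at least 2-fold lower, with an SD between probe sets of 0.33. There were 50 genes at least 4-fold higher and 0 at least 4-fold lower. A second probe set went the same way for 54 of 60 higher and 8 of 14 lower genes. The largest decreases with signal on both arrays were those of ALCAM, a cell adhesion molecule, at -1.64, HEATR3 at -1.5, TRDMT1 at -1.40, ART3 at -1.40 and CBX6, a Polycomb subunit, at -1.38, where the second CBX6 probe set gave -1.45. For EGR1 the probe sets differed in size, with 4.10 from the brighter and 1.33 from the other.

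Immediate early genes reached a median of 2.32 at 2 h, with 19 of 27 higher and 0 lower. MAPK feedback genes had a median of 0.63 with 5 of 17 higher, among them DUSP2 at 3.19 and DUSP10 at 2.66. Histone genes had a median of 1.51, with 18 of 23 higher and 0 lower, including H2AC6 at 4.79 and H2BC12 at 2.95. All 3 medians lay at percentile 100. The cytokine list had a median of 0.51 at percentile 99.98, with 6 of 19 higher, CXCL8 at 2.80 and TNF at 2.02, and its percentile was 90.0 without probe sets of the _s_at and _x_at kinds. The ATF4 and CHOP list had a median of 0.28 at percentile 99.94, with 5 of 23 higher and 0 lower. In it, ATF3 stood at 4.06, DDIT3 at 3.17 and PPP1R15A at 2.55. Its percentile was 97.0 without the same probe sets, and its median was -0.12 with hybridisation spike scaling. Zinc finger genes with numbered ZNF symbols had a median of 0.38 at percentile 100, with 12 of 157 higher and 2 lower, and a median of -0.03 with hybridisation spike scaling. The interferon-stimulated list had a median of 0.32 at percentile 98.6 with 1 of 19 higher, and with the floor at the 60th percentile the median of its 11 remaining members was -0.06. Hybridisation spike scaling put the full list at -0.11.

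Lower medians were small. Nuclear-encoded subunits of the respiratory chain had a median of -0.25 at percentile 0.025, yet 0 of 43 members reached 2-fold. Within the death receptor list 1 of 14 members was lower, the TNF receptor gene TNFRSF1A at -1.01. Of genes at the floor at 0 h, PTGS2 was at least 8.98-fold higher, the histone genes H2BC3 and H1-3 at least 6.81-fold and 4.69-fold, KLF2 at least 5.67-fold and HES1, a target of Notch signalling, at least 5.62-fold. A second HES1 probe set, above the floor on both arrays, gave a log2 ratio of 1.42, under the bound of 2.49 from the first.

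**Figure D3:**
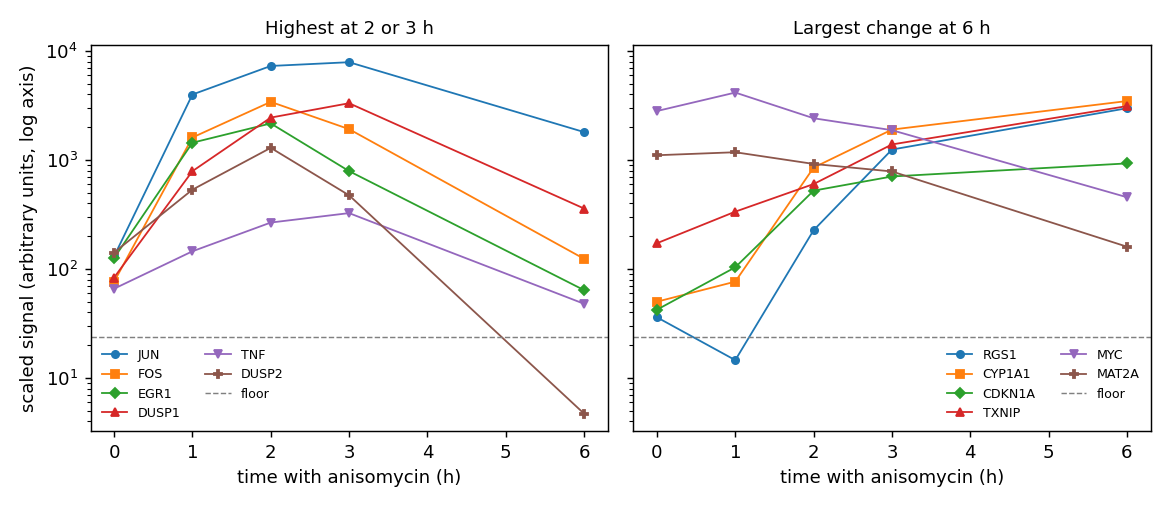
Scaled signal in arbitrary units on a log axis against time with anisomycin in hours, 1 array per time, with the floor of 23.8 as a dashed line. JUN, FOS, EGR1, DUSP1, TNF and DUSP2 (left) were highest at 2 or 3 h, whereas RGS1, CYP1A1, CDKN1A and TXNIP (right) were highest, and MYC and MAT2A lowest, at 6 h.

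At 3 h the largest ratios were those of JUN, 60.6-fold higher, H2AC6, 45.6-fold higher, and DUSP1, 39.8-fold higher. CYP1A1 was 38-fold and IER3 36.7-fold higher than at 0 h. FOS and EGR1 were nearer to their 0 h levels than at 2 h, with 25.2-fold and 6.28-fold. RGS1, a regulator of G protein signalling, was 34.6-fold higher by its brighter probe set, a log2 ratio of 5.11 against 2.19 from the other. TRIB1, a pseudokinase, was 18.7-fold higher.

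At this time 406 of 8220 genes were at least 2-fold higher and 141 were at least 2-fold lower, with an SD between probe sets of 0.33. A second probe set went the same way for 94 of 98 higher and 25 of 26 lower genes. At least 4-fold higher were 83 genes, and 1 was at least 4-fold lower. The transcriptional repressor gene BCL11A had a log2 ratio of -1.90, with -1.21 and -0.58 from its other probe sets. ALCAM had a ratio of -1.86 and WDR41 one of -1.68. APAF1, the scaffold of the apoptosome, stood at -1.60, with -0.76 from a second probe set. With arrays scaled on ribosomal protein genes, 661 genes were higher and 59 lower, so the split of calls at 3 h moved from 74.2% higher to 91.8% higher.

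Immediate early genes were at their highest median, 2.62, with 21 of 27 higher and 0 lower. MAPK feedback genes were at 0.86 with 6 of 16 higher, including DUSP10 at 3.81 and GADD45B at 2.15. Histone genes were at 1.74 with 17 of 23 higher and 0 lower. These 3 lists again lay at percentile 100. NF-κB targets had a median of 0.41 at percentile 99.9, with 4 of 20 higher and 1 lower, but one of -0.02 with hybridisation spike scaling. TNFAIP3, a feedback inhibitor of NF-κB, stood at 2.82, the urokinase gene PLAU at 2.38 and CD83 at 1.75. The list of cytokines had a median of 0.38 at percentile 99.8, with 7 of 19 higher, and TNF reached 2.31, but its percentile was 82.4 without the _s_at and _x_at probe sets. Of the ATF4 and CHOP list 6 of 23 members were higher, with DDIT3 at 3.66 and PPP1R15A at 3.11, at a list median of 0.12. DNA replication genes had a median of 0.17 at percentile 99.5, with 2 of 37 higher, CCNE2, which encodes a cyclin of S phase entry, at 1.58 and CDC6 at 1.08, where second probe sets gave 0.53 and 0.58. With hybridisation spike scaling the median was -0.26. Numbered zinc finger genes had a median of 0.39 at percentile 100, with 28 of 157 higher and 0 lower, and one of -0.02 with hybridisation spike scaling. Respiratory chain genes had a median of -0.30 at percentile 0.09, with 0 of 43 past 2-fold.

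From the floor, HES1 was at least 10.6-fold, PTGS2 at least 9.73-fold, HRH1, a histamine receptor gene, at least 9.44-fold and OSM, which encodes oncostatin M, at least 6.86-fold higher at 3 h. For HES1 the second probe set gave a log2 ratio of 2.46, under the bound of 3.41 from the first. EFNA3 was at least 3.29-fold lower.

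At 6 h RGS1 was 82.9-fold and CYP1A1 69.4-fold higher than at 0 h. FOS was 1.63-fold higher and EGR1 had a log2 ratio of -0.98, but other early genes stayed far above 0 h, with IER3 at 4.72, ATF3 at 4.70 and JUN at 3.79. TXNIP, an inhibitor of thioredoxin, was 18.1-fold higher, with log2 ratios of 3.43 to 3.67 from its other probe sets against 4.18. TNFSF14, a ligand of the TNF family, was 16.1-fold higher. MYC, a transcription factor of cell growth, was 6.18-fold lower, and MAT2A, the enzyme that makes S-adenosylmethionine, was 6.91-fold lower, a log2 ratio of -2.79 with -1.76 from a second probe set.

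At 6 h 693 of 8359 genes were at least 2-fold higher and 457 were at least 2-fold lower, with an SD between probe sets of 0.38. At least 4-fold higher were 121 genes, and 24 were at least 4-fold lower. A second probe set went the same way for 171 of 182 higher and 120 of 127 lower genes. Further large decreases were those of BCL11A at -2.65, the prostaglandin receptor gene PTGER2 at -2.62, KANK1 at -2.58, HERC2 at -2.48 and the lipoprotein receptor gene VLDLR at -2.47. With ribosomal protein scaling the split moved from 60.3% to 73.7% of calls higher.

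The apoptosis lists held members on both sides at 6 h. Among the pro-apoptotic BCL2 family genes 2 of 12 were higher, PMAIP1 (NOXA) at 1.58 and BCL2L11 (BIM) at 1.5, and 1 was lower, BNIP3 at -1.20. The other probe set of PMAIP1 gave 2.60, that of BCL2L11 gave 1.17 and that of BNIP3 gave -0.61. The family had medians of -0.18, -0.21, -0.17 and 0.03 at 1, 2, 3 and 6 h, at percentiles 3.6, 4.3, 18.9 and 58.7. Anti-apoptotic genes had medians of -0.03, 0.06, -0.06 and 0.47. At 6 h 3 of 12 were higher and 0 lower, with MCL1 at 1.48, BCL2A1 at 1.43 and XIAP at a bound of at least 2.15-fold. MCL1 was highest at 2 h, at 2.47. The percentile of the anti-apoptotic list at 6 h was 98.3, but it was 91.5 with the floor at the 25th percentile and 81.7 without the _s_at and _x_at probe sets, and the median was -0.01 with hybridisation spike scaling. CFLAR, an inhibitor of caspase 8, stayed between -0.15 and 0.37 at the 4 times. Of the death receptor list 3 of 14 members were higher, TNFRSF21 at 1.32, FADD, an adaptor, at 1.14 and the TRAIL receptor gene TNFRSF10B at 1.04, with 0.36 and 1.18 from its other probe sets, and TNFRSF1A was lower at -1.22. Of the caspase and executioner list 0 of 17 were higher and 2 were lower, CIDEB at -1.33 and the nuclease gene DFFB at -1.21, at a median of -0.28 and percentile 12.9.

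**Figure D4:**
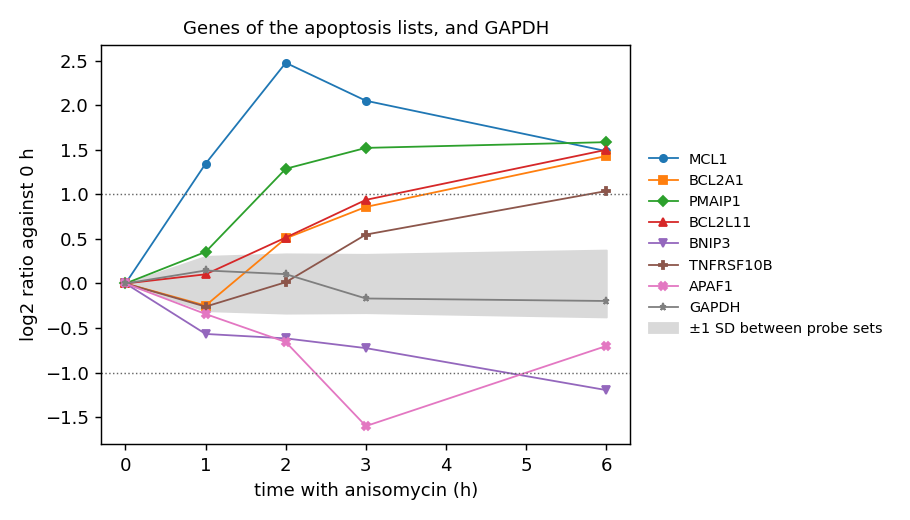
Log2 ratio against 0 h for genes of the apoptosis lists and GAPDH, by time with anisomycin in hours. Each point is 1 array pair relative to the bulk of the probe sets, the grey band is 1 SD between probe sets of a gene (0.30 to 0.38), and dotted lines mark 2-fold. MCL1 was highest at 2 h (2.47), PMAIP1 and BCL2L11 at 6 h (1.58 and 1.5), and GAPDH lay between -0.20 and 0.15.

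NF-κB targets had their highest median at 6 h, 0.76 at percentile 99.99, with 8 of 20 higher and 1 lower. TNFAIP3 stood at 3.67, PLAU at 2.56 and NFKBIE at 1.72. Of the cytokines 5 of 19 were higher and 1 lower, with IL1B at 2.48, CXCL8 at 2.11 and TNF at -0.46, at a median of 0.20. Immediate early genes had a median of 0.70, with 13 of 27 higher and 2 lower, and MAPK feedback genes one of 0.72, with 5 of 17 higher and 1 lower. The lower member was DUSP2, which was at least 5.94-fold lower at 6 h after a log2 ratio of 3.19 at 2 h. Histone genes had a median of 1.25 with 16 of 24 higher and 0 lower, and numbered zinc finger genes one of 0.46 with 30 of 162 higher and 3 lower. ZNF267 stood at 2.51 and ZNF200 at 2.49. The histone, zinc finger and immediate early medians lay at percentile 100 and the MAPK feedback median at 99.97.

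Cell cycle lists were slightly higher at 6 h. DNA replication genes had a median of 0.35 at percentile 99.98, with 3 of 37 higher and 0 lower, namely CCNE2 at 2.02, CDC6 at 1.58 and MCM10 at 1.36. Mitosis genes had a median of 0.26 at percentile 99.8, with 4 of 34 higher and 0 lower, namely CDK1 at 1.5, KIF23 at 1.33, CENPE at 1.20 and MKI67 at 1.05. The 3 other probe sets of MKI67 gave between -0.16 and 1.24. With hybridisation spike scaling the medians at 6 h were -0.13 for DNA replication and -0.21 for mitosis, so both directions hold only relative to the bulk of the probe sets. Genes of ribosome biogenesis had a median of -0.33 at percentile 2.16, with 0 of 30 higher and 5 lower, among them NOP16 at -1.44, NOL6 at -1.40, UTP20 at -1.13 and TAF1D at -1.04. The percentile of this list was 9.20 without the _s_at and _x_at probe sets. Respiratory chain genes had a median of -0.32 at percentile 0.87, with 0 of 43 higher and 2 lower, NDUFB7 at -1.60 and NDUFA3 at -1.06.

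Most other lists showed changes in single members rather than in the median at 6 h. Of the ATF4 and CHOP list 7 of 23 were higher and 2 lower, with ATF3 at 4.70, PPP1R15A at 2.74 and DDIT3 at 2.27 against VLDLR at -2.47. Of the NRF2 targets 1 of 14 was higher, SQSTM1, the autophagy adaptor p62, at 2.86. Of the cholesterol synthesis genes 1 of 19 was higher and 3 were lower, LSS at -1.61, MSMO1 at -1.34 and INSIG1 at -1.29, at a median of -0.20. Of the interferon-stimulated genes 2 of 20 were higher and 4 lower, with IRF1 at 1.41 and IRF7 at 1.17 against IFITM1 at -1.29 and ISG15 at -1.11. Of the stress kinases 0 of 17 were higher and 1 lower, the RNA-dependent kinase gene EIF2AK2 at -1.52, for which a second probe set gave -0.47. Of the mRNA decay factors 3 of 28 were higher, ZFP36 at 1.61, CNOT4 at 1.58, with 0.29 from a second probe set, and BTG1 at 1.44. Of the translation factors 1 of 33 was higher, EIF5 at 1.51, and 1 lower, EIF4EBP1 at -1.03. Without the _s_at and _x_at probe sets EIF5 stood at -0.48. Of the monocytic markers 3 of 21 were higher, with SPI1 at 1.48, CEBPB at 1.22 and S100A8 at 1.17, and 3 were lower, among them CEBPA at -1.22. The snoRNA host genes were an exception, with medians of 0.40, 0.64, 0.39 and 0.92 at 1, 2, 3 and 6 h, but only 3 were measured, and the percentile was 97.54 at 2 h, just apart from random lists, and 97.36 at 6 h, just short of it. At 6 h SNHG32 was at 1.10, SNHG17 at 0.92 and TAF1D at -1.04.

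The remaining lists stayed within 2-fold with few exceptions. None of the 51 cytosolic ribosomal protein genes reached 2-fold at 2, 3 or 6 h, and their medians at 1, 2, 3 and 6 h were 0.09, -0.06, -0.22 and -0.14. The value at 1 h was -0.01 after quantile normalization. Proteasome genes had medians of -0.04, -0.12, -0.22 and -0.20 with 0 of 31 past 2-fold at each time, although the 3 h value was 0.01 with ribosomal protein scaling. Heat shock genes had medians of 0.03, 0.04, -0.13 and -0.12, and DNAJB1 was at 1.85 at 2 h and 0.06 at 6 h. Reference genes had medians of 0.07, 0.12, -0.0049 and 0.05, and 1 of 15 was past 2-fold at 6 h, PPIB at -1.16. GAPDH lay between -0.20 and 0.15 and ACTB between -0.21 and -0.02. Markers of other cell types had medians of -0.03, -0.08, -0.08 and -0.10 in 8 to 11 measured members, with a median signal at 0 h of 26.7 to 37.3 units, and KRT8 at 2 h, at 1.15, was the only member past 2-fold. At 1 or more times, the sign of a small median differed between the scalings that do not use spikes for all 4 apoptosis lists and for the lists of stress kinases, ATF4 and CHOP stress, heat shock proteins, NRF2 targets, interferon-stimulated genes, ribosomal proteins, ribosome biogenesis, translation factors, mRNA decay, mitosis, DNA replication, cholesterol synthesis, the proteasome, monocytic markers, other cell types and reference genes. None of these changes of sign concerned the mitosis, DNA replication, anti-apoptotic or ribosome biogenesis medians at 6 h.

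**Figure D5:**
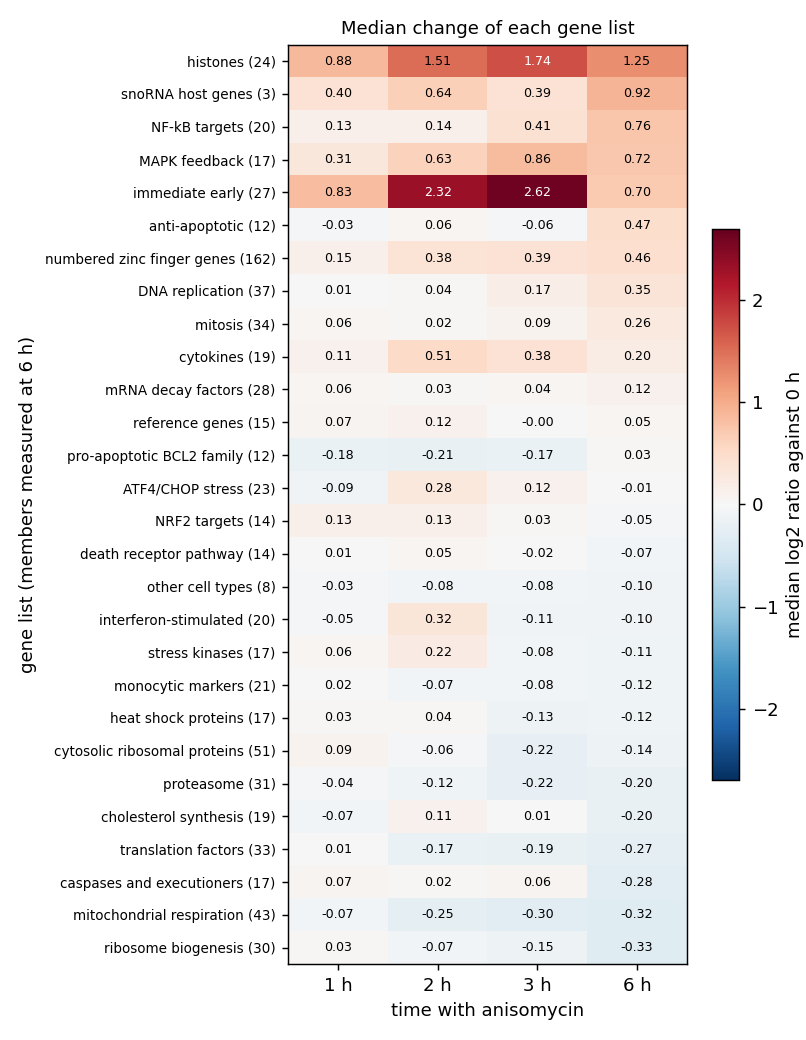
Median log2 ratio against 0 h of 28 gene lists (rows, with the members measured at 6 h in brackets) at 4 times with anisomycin (columns), 1 array per time. Immediate early genes have the highest medians at 2 and 3 h (2.32 and 2.62) and histones at 6 h (1.25); values are relative to the bulk of the probe sets, whose median gene would be at -1.49, -1.56 and -1.41 at 2, 3 and 6 h with poly-A spike scaling, and medians near 0 change sign between scalings.

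Across the series 1489 genes were at least 2-fold changed at 1 or more times. The largest change fell at 6 h for 567 of the genes whose largest change was an increase and for 419 of those whose largest change was a decrease. Of the 546 genes that were at least 2-fold higher at 1, 2 or 3 h, 336 were still at least 2-fold higher at 6 h. Of the remaining 210, 2 were at least 2-fold lower at 6 h, DUSP2 and FOSL1, the latter named after its values were seen. At all 4 times 41 genes were higher and 3 lower. Steps in a single direction at every interval, adding up to at least 2-fold, were found for 203 genes upward and 119 downward. The real order of the arrays gave the largest total, 322, of the 60 possible orders, and the highest other order gave 271, with 0 and 1 h exchanged. For upward steps alone no other order gave as many, but for downward steps alone another order gave 138, more than the real one.

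Between 3 and 6 h 308 higher genes and 72 lower genes were shared. Independent lists of these sizes would share 34.3 and 8.05, and simulated unchanged arrays against the same 0 h array shared 1.24 and 1.20. The log2 ratios of the 2 times correlated across genes with r = 0.775 against a simulated 0.499, and their covariance was 0.347 against 0.0586. At 1 h the match with later times was weaker, with r = 0.548, 0.450 and 0.337 for 1 h against 2, 3 and 6 h, where simulation gave 0.499 to 0.501, and covariances of 0.105, 0.102 and 0.0945 against 0.0483, 0.0479 and 0.0549. The simulated correlation is fixed by the shared 0 h array and equal noise on each array, whatever the size of the noise. An r under it therefore does not mean a weaker match than between unchanged arrays. Genes are not independent replicates. Between 1 and 2 h 64 higher and 7 lower genes were shared, against 3.32 and 0.37 for independent lists and 0.23 and 0.33 in simulation. Part of each excess may come from the shared 0 h array, which could not be split. With the 1 h array as the reference, 598 genes were at least 2-fold higher and 508 lower at 6 h.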

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

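All tests of the spike controls and the tests of DNA replication genes and of weak signals for the histones were chosen after the results had been seen; the other tests of the histone and zinc finger genes were set before.

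The poly-A spikes belong to no comparison of gene expression, yet their scaled signal stepped up between 1 and 2 h. Their median log2 ratio against 0 h was 0.36 at 1 h, 1.56 at 2 h, 1.64 at 3 h and 1.57 at 6 h, with all 24 probe sets higher at each of the last 3 times. On scaled signals the hybridisation spikes reached at most 0.321 of the poly-A change. That fraction by itself could not decide on a brighter hybridisation of the whole array, because scaling to a common trimmed mean removes a uniform change. For the same reason a uniformly brighter array cannot produce the step that remains in the scaled signals. In the deposited signals the poly-A medians were 0.95, 1.47 and 1.11 higher at 2, 3 and 6 h than at 0 h. Those of the hybridisation spikes were at -0.24, 0.27 and 0.04, which argues against a brighter array as the sole cause of the change in deposited signals. A different amount of spike in the later preparations is a candidate explanation, since the medians at 2, 3 and 6 h lay within 0.0812 of each other after a step of 1.19 from 1 to 2 h. Less messenger RNA in the total RNA from 2 h on, which is the biological reading of the time course, cannot be told apart from it. Ribosomal RNA control probe sets had medians of -0.08, 0.32 and -0.37 at 2, 3 and 6 h, with 5, 8 and 6 of 12 higher. These lay below the median of 1 or more set for this reading, but their median plus 1 SD was up to 1.44, too scattered to decide.

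The histone genes had a median of 1.25 at 6 h with 16 of 24 past 2-fold and 0 lower. Weak signals near the floor as the cause are argued against, since the median lay at percentile 100 of random lists matched on the 0 h signal, whose own median was 0.20; a test set before, on members above the floor on both arrays, was dropped because that filter depends on the change. A larger share of cells in S phase is argued against as the main cause at 1 and 2 h. There DNA replication members went both ways, with medians of 0.01 and 0.04 against 0.88 and 1.51 for histones. The bootstrap intervals of these DNA replication medians were -0.07 to 0.09 and -0.11 to 0.12. The bound set for 2 h, an upper end under 0, was not met, but it asked for a fall of these genes. At 6 h this reading stays open, as DNA replication members were slightly higher, with an upper end of 0.505. Probes shared between histone paralogs stay open: the 12 histone probe sets of the plain _at kind had a median of 0.789, with 5 of 12 past 2-fold, between the bounds set for either reading. An effect of anisomycin on histone transcripts, such as on their stability or on polyadenylated forms, was not tested.

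The numbered zinc finger genes had a median of 0.46 at 6 h. An intensity-dependent array response is argued against, because the median was 0.476 over 166 members after cyclic loess. Probes shared between zinc finger paralogs are argued against as well, since the 115 plain _at probe sets had a median of 0.484. An effect of the treatment may remain as a hypothesis, but only relative to the bulk of the probe sets, since the median was 0.02 with hybridisation spike scaling.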

How the results depend on the processing

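Both spike scalings and support from a second probe set were chosen after seeing the data. Leaving out a replicate was not possible with 1 array per time. No paired analysis was possible because each time has 1 array and no test was run. The following counts of genes past the mark differed by more than 1.5 times from the main ones, in the order 1, 2, 3 and 6 h unless stated.

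A mark of 1.5-fold gave 612, 947, 1029 and 1545 higher and 311, 520, 826 and 1451 lower genes, and one of 3-fold gave 26, 84, 154 and 234 higher and 1, 1, 8 and 75 lower, which follows from the marks themselves. A floor at the 25th percentile gave 601, 784, 684 and 1130 higher and 305, 390, 456 and 803 lower. A floor at the 60th percentile gave 35, 134 and 265 higher at 1, 2 and 3 h and 4, 14, 46 and 242 lower. No floor gave 1189, 1356, 1251 and 1684 higher and 714, 839, 960 and 1304 lower. Weak signals thus decide many of the calls, most of all at 1 h. Hybridisation spike scaling gave 126, 193 and 296 higher at 2, 3 and 6 h and 71, 475, 830 and 1637 lower. Poly-A spike scaling gave 33, 54 and 67 higher at 2, 3 and 6 h and 366, 6918, 6832 and 6175 lower. Ribosomal protein scaling gave 661 higher and 59 lower at 3 h and 66 genes falling at every interval, against 119. Support from a neighbouring time left 13 lower genes at 1 h and 240 at 6 h. Leaving out _s_at and _x_at probe sets left 178 higher genes at 2 h, from fewer probe sets. Except where a cause is named, the cause was not tested.

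The share of calls that were higher was 74.4, 78.9, 74.2 and 60.3% in the main setting. A floor at the 60th percentile gave 89.7, 90.5, 85.2 and 66.0% at 1, 2, 3 and 6 h, one at the 25th percentile 66.3, 66.8, 60 and 58.5%, and no floor 62.5, 61.8, 56.6 and 56.4%. The 1 h array as the reference gave 64.7, 65.9 and 54.1% at 2, 3 and 6 h. The share was 65.0% at 1 h after cyclic loess, 62.8 and 68.3% at 1 and 2 h after quantile normalization, 60.9, 91.8 and 73.7% at 1, 3 and 6 h with ribosomal protein scaling, 20.97, 18.9 and 15.3% at 2, 3 and 6 h with hybridisation spike scaling, and 30.0, 0.47, 0.78 and 1.07% with poly-A spike scaling. With the other scalings and choices of probe sets it lay at 68.7 to 77.3%, 71.8 to 81.4%, 71.7 to 75.9% and 56.7 to 63.5% at 1, 2, 3 and 6 h.

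Under the alternatives without spikes, signs were compared for list medians and for up to 222 of the 617 named gene values per alternative. Among the compared gene values past 2-fold and list medians apart from random lists, signs turned for 4, and the cause was not tested. The signs of other genes past 2-fold were not compared, so 4 is not a count over all calls. Genes named for the largest changes above the floor had also been chosen with their other probe sets going the same way. Smaller values changed sign more often, and of 33 list medians apart from random lists poly-A spike scaling turned 21 and hybridisation spike scaling 9. The interferon list at 2 h was at -0.065 with the floor at the 60th percentile, the ribosomal protein list at 1 h at -0.0096 after quantile normalization, CYP2D6 at 2 h at 0.045 against the 1 h array and EIF5 at 6 h at -0.48 without _s_at and _x_at probe sets. Of the other values of lists under the alternatives without spikes, 1126 stayed within their bootstrap interval and 65 moved out of it, and of those of named genes 1788 stayed within 1 SD between probe sets and 260 moved by more. Of 33 list medians apart from random lists, between 0 and 8 lost this under any 1 alternative without spikes, with 8 lost of 32 without _s_at and _x_at probe sets. Signal near the floor limits the folds of dim genes.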

Other observations

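The tests of aryl hydrocarbon receptor targets were chosen after the results had been seen, and the splicing factor test was set before its result but after CLK1 had been noticed. Apart from CYP1A1, DUSP2, IL1B and PTGS2, genes named in this part were chosen after their values were seen.

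Over all genes, 4 were past 2-fold in both directions. DUSP2 went from 3.19 at 2 h to -2.57 or lower at 6 h, where it lay at the floor, and FOSL1 went from 1.18 to -1.09. SCYL2 went from -1.09 at 1 h to 1.65 at 6 h, and TREM1, a receptor of myeloid cells, from -1.01 to 1.84. Of 3150 probe sets with several symbols or none, 39, 79, 76 and 111 were at least 2-fold higher at 1, 2, 3 and 6 h, and 13, 29, 41 and 103 lower.

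CYP1A1 had log2 ratios of 0.61, 4.09, 5.25 and 6.12 at 1, 2, 3 and 6 h, and TIPARP, another target of the aryl hydrocarbon receptor, had 1.43, 3.01, 3.58 and 2.83. A rise of receptor targets in general may be present, although only 9 of 16 other listed targets were measured at 6 h. At 1, 2 and 3 h the median of the other measured targets lay at percentiles 32.7, 94.0 and 92.9, not apart from random lists. At 6 h their median was 0.61, at percentile 99.12 of matched random lists, with 3 past 2-fold higher and 1 lower. The 3 were IL1B at 2.48, PTGS2 at a lower bound of 2.23 and NFE2L2 at 1.59, and SLC7A5 was at -1.23. All of these also respond to other pathways. Without IL1B and PTGS2 the percentile was 97.31 over 7 members, just short of the upper mark for lists apart from random ones, so the hypothesis leans on these 2 genes. CYP1A2 stood at -0.14 and NQO1 at 0.24. CYP1B1 was not measured at 6 h, and ALDH3A1, under the floor at 0 h, counts only because it was above the floor at 6 h.

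CLK1, a kinase of splicing factors, had log2 ratios of 0.99, 2.01, 2.57 and 3.42. A candidate explanation is a rise of transcripts with poison exons, which translation-dependent decay removes in untreated cells. The median of 13 other such genes was 0.35 at 6 h, at percentile 99.11, and the percentiles at 2 and 3 h were 99.5 and 99.7. These values are relative to the bulk of the probe sets and were not computed with spike scaling. Hybridisation spike scaling placed the median gene at -0.48 at 6 h. Only 2 of the 13 were past 2-fold at 6 h, CLK4 at 1.88 and SRSF10 at 1.22. The array probes do not separate isoforms, so the inclusion of the exons was not measured.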
